A study of Homo sapiens with 26 samples.

How the data were processed

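The deposited file holds expected counts per gene from RNA sequencing, which, per the submitters' processing notes, came from alignment with Bowtie2 and quantification with RSEM on hg38; the authors gave no versions of these tools. Of the values, 4.86% were not whole numbers, as RSEM divides reads that fit several genes, and counts were rounded to whole numbers before testing. The file lists 18968 genes, of which 18905 (99.7%) matched the reference gene table and 99.3% were protein coding. It also holds FPKM, TPM and normalised read counts of the same libraries, and averages per group. These 106 columns were not used, because the tests need counts.

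Differences were tested with edgeR 4.0.16 on R 4.3.3. Counts were scaled by the TMM method, genes with too few counts were removed by filterByExpr with its minimum count of 10, and a quasi-likelihood model with 1 mean per group was fitted to all 26 libraries. The 15359 genes kept were tested in 10 comparisons, each adjusted by Benjamini and Hochberg over all tested genes, and called at an adjusted p below 0.05 and at least 2-fold. Log2 CPM used a prior count of 2, and fold changes used the default prior count of the edgeR fit. The SE of a log2 fold change is its size divided by the root of the F statistic. CPM are counts-per-million values of the TMM-scaled library size. Correlations between libraries and principal components used log2 CPM. Interaction tests compared 2 derivations by their difference of log2 fold changes in the same model.

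In all, 28 gene lists were fixed, of which 27 had at least 5 tested genes, and 38 anchor genes, of which 2 are not in the file. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01 between genes and with that estimated from the data, adjusted over the lists of a comparison. Counts per list were not tested against all genes and were also made with p adjusted over the list alone. Camera was also applied to the genes of each of chromosomes 1 to 22 and X with at least 50 tested genes (15337 have coordinates), with p adjusted over all chromosomes and comparisons. A chromosome was called shifted at an adjusted p below 0.05 and a median log2 fold change at least 0.2 from that of all autosomal genes. Each TSC library was set against the other 15 in the same way. Coordinates are those of the GRCh38.p14 annotation.

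The genes named are, for each comparison, the 6 with the largest increase and the 6 with the largest decrease among called protein-coding genes with a mean of at least 20 CPM in the higher group and no overlap between the 2 sides. To these were added the anchor genes, up to 4 members of each described list with the smallest p, and the 3 members with the smallest p of a shifted chromosome. Genes given for libraries that stand apart were chosen after their values were seen. Groups, comparisons, lists, thresholds and the rule for named genes were chosen before the data were examined, and so were the alternatives, except where the text says otherwise.

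Replicate numbers may pair nRUES2 and RUES2 libraries: after group means were taken out, libraries of equal number correlated across genes with r between 0.198 and 0.327 (median 0.223). In no other comparison did the numbers pair the libraries. The labels name no batch. The p-values measure only the spread between these libraries of a single line, not between lines or donors. Floors for genes with no count are 3 counts over the group and cover counting error only.

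Steps were tested on counts simulated by a negative binomial model with these data's dispersions and library sizes. Here 200 genes changed 2-fold or 4-fold. At an adjusted p below 0.05, 43% of the 2-fold and 80% of the 4-fold changes were found for nRUES2 against RUES2, and 1.6% of the calls were false. These shares were 29%, 78% and 1.83% for nTSC against nRUES2 and 74%, 92% and 3.49% for naive-derived against primed-derived TSC. For pdTSC against ccTSC they were 47%, 88% and 5.59%. For chromosomes, a 1.5-fold gain was found as log2 0.549 and a 1.25-fold loss as -0.271, with 0 false calls in 368 tests. Genes were drawn independently, so this gives no false-call rate for real data.

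The alternatives run were DESeq2 1.42.0, RLE scaling, no filter and a minimum count of 50, a fit of only the groups of a comparison, the replicate number as a block, leaving out each library, and the estimated correlation. Added after the data were seen were the counts without pdTSC 1 and 3 and the chromosomes without zinc finger genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.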

Results

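Gene expression was measured by RNA sequencing in 26 libraries from a single human pluripotent stem cell line, RUES2, and from cells derived from it, so that all groups shared one genetic background. RUES2 in the primed state (n = 3), which resembles the epiblast after implantation, and its naive counterpart nRUES2 (n = 3), which resembles the epiblast before implantation, were the starting cells. Trophoblast stem cells (TSC), the self-renewing progenitors of the placental epithelium, had been made by 4 routes with n = 4 libraries each. The nTSC came directly from naive cells and the nbTSC from blastoids, which are embryo-like structures grown from naive cells. The ccTSC came from primed cells by chemical conversion and the pdTSC from primed cells through trophectoderm-like cells. BAP cells (n = 4) were a trophoblast differentiation of primed cells. The total count per library lay between 13188358 and 18328206, and 15359 of the 18968 genes listed passed the expression filter and were tested. Levels are counts-per-million values (CPM), as mean ± SD over these numbers of libraries. A gene was called up- or downregulated at an adjusted p below 0.05 and a change of at least 2-fold. Where a group had no count of a gene in any library, the fold is a lower bound computed against 3 counts over the whole group, and it covers counting error only.

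The pluripotent, TSC and BAP libraries separated on the first 2 principal components, which held 42.0% and 23.7% of the variance of log2 CPM. The pluripotent libraries lay at one end of the first component and the 16 TSC libraries at the other, with BAP cells between them on the first component and apart from all others on the second. The mean correlation of log2 CPM across genes was 0.976 between nTSC and nbTSC libraries and 0.962 between ccTSC and pdTSC libraries, against 0.938 to 0.954 between naive-derived and primed-derived TSC and 0.857 to 0.877 between BAP cells and TSC. Within groups it was lowest among pdTSC (0.950). After the mean over the TSC libraries was taken out, the nearest library of pdTSC 3 was nbTSC 3 (r = 0.466). That of pdTSC 1 was ccTSC 2 (r = 0.298), that of pdTSC 2 was ccTSC 1 (r = 0.773) and that of pdTSC 4 was ccTSC 2 (r = 0.712). These correlations are across genes, which are not independent replicates.

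**Figure D1:**
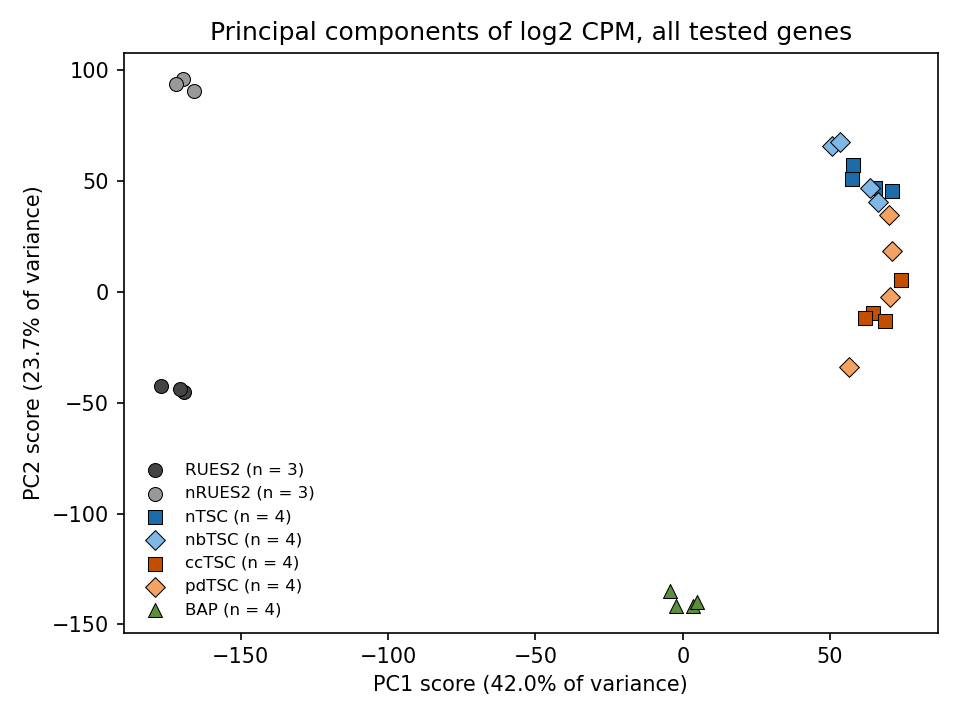
Scores of the 26 libraries on the first 2 principal components of log2 CPM (no unit), 1 point per library, with colour and shape giving the group. TSC libraries of all 4 routes lie together on the first component, which holds 42.0% of the variance, and BAP cells lie apart from the other groups on the second, which holds 23.7%.

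**Figure D2:**
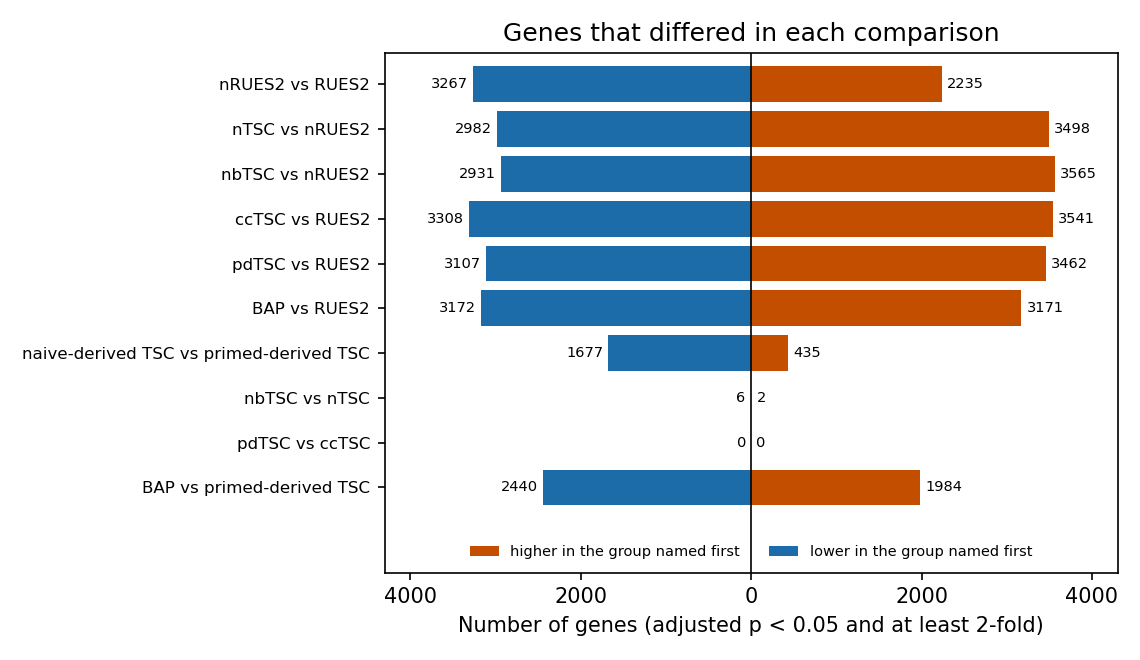
Number of genes called in each of the 10 comparisons, with genes higher in the group named first to the right of 0 and genes lower in it to the left. Each comparison of TSC or BAP cells with their pluripotent cells has at least 6343 genes, nbTSC against nTSC has 8 and pdTSC against ccTSC has 0.

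Naive and primed pluripotent cells were compared first, because the TSC routes start from one or the other. Both states held the pluripotency factor *POU5F1* at the same mean level (1876 ± 39.4 against 1877 ± 309 CPM, adjusted p = 1). *NANOG*, another factor of the core network, was higher in naive cells (338 ± 13.7 against 66.5 ± 40.5 CPM, adjusted p = 2.35e-05). *SOX2* was lower (106 ± 14.5 against 337 ± 39.6 CPM, adjusted p = 0.000185). The largest increases in naive cells were in *KHDC1L* (949 ± 71.5 against 0.0161 ± 0.0278 CPM), in the zinc finger genes *ZNF729*, *ZNF257* and *ZNF727*, in the thioesterase gene *OLAH* and in *TRIM60*. RUES2 had no count of these last 5 genes, so that *ZNF729* was at least 3907-fold and *OLAH* at least 2315-fold higher. The largest decreases were in *SPRY4*, *GRPR*, *COL11A1* and 3 further genes. *SFRP2*, which encodes a secreted Wnt antagonist, and the receptor phosphatase gene *PTPRZ1* were at 0.0693 ± 0.0685 against 266 ± 47.9 CPM and 0.0702 ± 0.071 against 232 ± 15.3 CPM. *THY1*, a surface marker of primed cells, was at 0.163 ± 0.147 against 308 ± 109 CPM (log2 fold change -10.83, SE 0.91, adjusted p = 2.84e-09). In all, 2235 genes were upregulated and 3267 downregulated in nRUES2 compared to RUES2.

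Of the 24 measured naive pluripotency genes, 23 were higher in nRUES2, 0 were lower and 1 did not pass (camera adjusted p = 2.25e-20, or adjusted p = 2.36e-05 with an estimated correlation). Among them were *DPPA5* (1019.6 ± 33.5 against 1.19 ± 0.31 CPM, adjusted p = 2.16e-10) and the DNA methylation cofactor gene *DNMT3L* (1534 ± 195 against 0.282 ± 0.0317 CPM, adjusted p = 9.37e-10). The growth factor gene *FGF4* (325 ± 18.8 against 1.2 ± 0.267 CPM, adjusted p = 1.89e-12) and the transcription factor gene *KLF17* (36.2 ± 7.33 CPM, at least 730-fold higher) were among them too. All 17 measured primed pluripotency genes were lower (camera adjusted p = 2.47e-14, or adjusted p = 2.36e-05 with an estimated correlation). *ZIC2* (0.30 ± 0.148 against 57.9 ± 8.67 CPM, adjusted p = 7.82e-09) and *CD24* (52.5 ± 9.77 against 2488 ± 153 CPM, adjusted p = 2.22e-10) are examples. The core pluripotency list went both ways, with 8 members higher, 6 lower and 6 not passing (camera adjusted p = 0.663, or adjusted p = 0.906 with an estimated correlation). *TERF1*, a telomere-binding protein gene, was among the lower ones (77.1 ± 5.82 against 1031 ± 93.4 CPM, adjusted p = 1.14e-13).

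Germline genes were higher in naive cells for 13 of 21 members, lower for 2 and not passing for 6 (camera adjusted p = 0.000605, or adjusted p = 0.358 with an estimated correlation). They included *MAEL*, a gene of the piRNA pathway (21.6 ± 1.19 against 0.20 ± 0.149 CPM, adjusted p = 6.61e-07), and the synaptonemal complex gene *SYCE1* (at least 128-fold). The autophagy list had 9 higher, 1 lower and 38 not passing (camera adjusted p = 0.0128, or adjusted p = 0.731 with an estimated correlation). The conjugation enzyme gene *ATG3* led them (701 ± 28.9 against 59 ± 3.21 CPM, adjusted p = 1.62e-13). The unfolded protein and integrated stress response list had 8 higher, 1 lower and 17 not passing (camera adjusted p = 0.0128, or adjusted p = 0.899 with an estimated correlation). *TRIB3* was the member of smallest p (243 ± 10.9 against 16.6 ± 1.98 CPM, adjusted p = 2.89e-11). Ribosomal protein genes had 2 higher, 0 lower and 53 not passing (camera adjusted p = 0.000605, or adjusted p = 0.899 with an estimated correlation). The trophoblast lists did not pass camera and went both ways. Cytotrophoblast and trophoblast stem genes had 11 higher, 7 lower and 9 not passing (adjusted p = 0.0591, or adjusted p = 0.731 with an estimated correlation). Syncytiotrophoblast genes had 7 higher, 2 lower and 18 not passing, or 14 and 2 called by DESeq2 (adjusted p = 0.169, or adjusted p = 0.906 with an estimated correlation). Extravillous genes had 3 higher, 9 lower and 10 not passing (adjusted p = 0.236, or adjusted p = 0.899 with an estimated correlation). *GATA3* stood at 4.59 ± 0.85 against 0.266 ± 0.108 CPM and the placental gene *ERVH48-1* at 368 ± 66.5 against 5.13 ± 1.67 CPM. Adjusted over the list alone, every list of this comparison gave the same counts. Over all comparisons, 102 list calls were made with the preset correlation, and 17 of them held with an estimated one. All 17 were in the core, primed or naive pluripotency and the cytotrophoblast lists.

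The direct route from naive cells was examined by comparing nTSC with nRUES2. *POU5F1* fell in nTSC, to 0.224 ± 0.14 against 1876 ± 39.4 CPM (log2 fold change -12.97, SE 0.64, adjusted p = 1.4e-13). *TDGF1*, a co-receptor gene of the Nodal pathway, had no count in any nTSC library against 463 ± 40.9 CPM in nRUES2 (at least 10894-fold lower). *KHDC3L*, *PRDM14*, *APELA*, *UTF1* and *CNR2* were likewise without a count in nTSC and at least 1426-fold lower. The transcription factor genes *GATA2* (619 ± 146 against 8.73 ± 2.23 CPM, adjusted p = 9.7e-13) and *GATA3* (268 ± 50.1 against 4.59 ± 0.85 CPM, adjusted p = 1.37e-12) rose. *TP63*, a factor of epithelial stem cells, rose as well (40.6 ± 13 against 0.254 ± 0.107 CPM, adjusted p = 2.15e-10). So did the epithelial keratin gene *KRT7* (970.0 ± 191 against 1.27 ± 0.224 CPM, adjusted p = 4.69e-12) and the growth factor receptor gene *EGFR* (255 ± 15.4 against 1.91 ± 0.429 CPM, adjusted p = 4.78e-14). *SIGLEC6*, a sialic acid-binding lectin gene expressed in placenta, went from no count to 271 ± 24.8 CPM (at least 3925-fold higher). *PRKAA2*, *XAGE3*, *SERPINB7*, *GBP2* and *KRT14* were the other genes with the largest increases. In all, 3498 genes were upregulated and 2982 downregulated in nTSC compared to nRUES2.

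The cytotrophoblast and trophoblast stem list had 22 of 27 members higher, 1 lower and 4 not passing (camera adjusted p = 1.86e-11, or adjusted p = 0.00285 with an estimated correlation). The lower one was *CDX2*, a regulator of early trophectoderm (0.0421 ± 0.0541 against 1.17 ± 0.472 CPM). Core pluripotency genes were lower for 18 of 20, and 2 did not pass (camera adjusted p = 1.46e-12, or adjusted p = 0.00714 with an estimated correlation). Naive pluripotency genes were lower for 20 of 24, and 4 did not pass (camera adjusted p = 1.72e-10, or adjusted p = 0.00285 with an estimated correlation). Genes of the hormone-producing syncytiotrophoblast were higher for 23 of 27 and did not pass for 4 (camera adjusted p = 9.09e-06, or adjusted p = 0.521 with an estimated correlation). *CGA*, the shared subunit of glycoprotein hormones, varied widely between nTSC libraries (772 ± 773 against 8.44 ± 2.44 CPM, adjusted p = 0.00355), and the syncytin gene *ERVW-1* less so (208 ± 67.9 against 10.1 ± 0.996 CPM, adjusted p = 6.56e-06). Extravillous trophoblast genes, of the invasive lineage, were higher for 15, lower for 1 and not passing for 6, or 16 and 2 adjusted over the list alone (camera adjusted p = 0.000843, or adjusted p = 0.266 with an estimated correlation). Among them were *HLA-G* (54 ± 23.2 against 1.79 ± 0.0455 CPM, adjusted p = 1.44e-08) and the protease inhibitor gene *TIMP3* (1013 ± 321 against 3.45 ± 1.03 CPM, adjusted p = 2.46e-10).

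Lysosome genes were higher for 20 of 33, lower for 3 and not passing for 10 (camera adjusted p = 0.000273, or adjusted p = 0.59 with an estimated correlation). The protease gene *CTSH* led them (477 ± 127 against 2.39 ± 0.184 CPM, adjusted p = 3.85e-11). The endogenous retroviral envelope and capsid list had 7 of 8 higher and 1 not passing (camera adjusted p = 0.013, or adjusted p = 0.521 with an estimated correlation). Cohesin genes were lower for 5 of 17 with 12 not passing (adjusted p = 0.0264, or adjusted p = 0.679 with an estimated correlation). Germline genes were lower for 9 of 21 with 1 higher and 11 not passing (adjusted p = 0.0069, or adjusted p = 0.521 with an estimated correlation). DNA replication genes were lower for 14 of 34 with 1 higher and 19 not passing (adjusted p = 0.000392, or adjusted p = 0.874 with an estimated correlation). Of the ribosomal protein genes, 3 of 55 were lower and 52 did not pass (adjusted p = 0.000335, or adjusted p = 0.879 with an estimated correlation). The cohesin members with the largest falls, *REC8* (2.57 ± 1.17 against 113 ± 3.4 CPM, adjusted p = 1.58e-08) and *STAG3*, encode meiotic subunits. Among anchor genes of the cell cycle, the tumour suppressor gene *TP53* fell (19.7 ± 3.85 against 64.4 ± 6.4 CPM, adjusted p = 2.03e-06) and its target *CDKN1A* rose (408 ± 119 against 47.4 ± 13.7 CPM, adjusted p = 5.14e-08). The spindle checkpoint gene *MAD2L1* fell (62.4 ± 13.4 against 169 ± 15.7 CPM, adjusted p = 9.59e-06). *BUB1B*, another gene of that checkpoint, did not pass (log2 fold change 0.11, SE 0.25, adjusted p = 0.726). Except for the extravillous list, the counts adjusted over the list alone were the same.

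The blastoid route gave a close counterpart when nbTSC were set against nRUES2. *POU5F1* (0.0542 ± 0.0752 against 1876 ± 39.4 CPM) and the Nodal pathway genes *TDGF1* and *NODAL* were lost, *NODAL* from 273 ± 50.2 CPM to no count (at least 6278-fold lower). *GATA2* (766 ± 148 against 8.73 ± 2.23 CPM, adjusted p = 5.72e-13) and *GATA3* (315 ± 80.5 against 4.59 ± 0.85 CPM, adjusted p = 8.21e-13) rose. So did *KRT7* (573 ± 277 against 1.27 ± 0.224 CPM, adjusted p = 1.07e-11) and the integrin gene *ITGB4* (516 ± 156 against 2.14 ± 0.558 CPM, adjusted p = 6.31e-14). *SIGLEC6* again rose from no count, to 182 ± 37.8 CPM (at least 2646-fold), and *XAGE3*, of a gene family with near-identical copies, to 137 ± 73.1 CPM. In all, 3565 genes were upregulated and 2931 downregulated in nbTSC compared to nRUES2.

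Cytotrophoblast and trophoblast stem genes were higher for 24 of 27, lower for 1 and not passing for 2 (camera adjusted p = 8.88e-12, or adjusted p = 0.00246 with an estimated correlation). Core pluripotency genes were lower for 18 of 20 with 2 not passing (camera adjusted p = 3.75e-13, or adjusted p = 0.00577 with an estimated correlation). Naive pluripotency genes were lower for 18 of 24 with 6 not passing (camera adjusted p = 1.67e-10, or adjusted p = 0.00246 with an estimated correlation). Syncytiotrophoblast genes were higher for 18 of 27 and not passing for 9, or 19 higher adjusted over the list alone (camera adjusted p = 0.000299, or adjusted p = 0.709 with an estimated correlation). *CGA* stood at 168 ± 97.9 against 8.44 ± 2.44 CPM (log2 fold change 4.31, SE 1.61, adjusted p = 0.0254). Extravillous genes had 14 higher, 2 lower and 6 not passing (camera adjusted p = 0.00186, or adjusted p = 0.342 with an estimated correlation). *HLA-G* was among the first (65.4 ± 27.5 against 1.79 ± 0.0455 CPM, adjusted p = 6.92e-09). Lysosome genes had 21 higher, 3 lower and 9 not passing (camera adjusted p = 0.000299, or adjusted p = 0.692 with an estimated correlation). The endogenous retroviral list had 6 of 8 higher and 2 not passing (camera adjusted p = 0.0174, or adjusted p = 0.628 with an estimated correlation). It includes *PEG10*, a capsid-derived gene needed for placental growth in mice (2892 ± 1139 against 99.5 ± 10.7 CPM, adjusted p = 1.72e-06). Cohesin genes had 5 of 17 lower and 12 not passing (adjusted p = 0.0428, or adjusted p = 0.775 with an estimated correlation), and germline genes 10 of 21 lower and 11 not passing (adjusted p = 0.00231, or adjusted p = 0.418 with an estimated correlation). DNA replication genes had 12 of 34 lower, 1 higher and 21 not passing (adjusted p = 0.000683, or adjusted p = 0.831 with an estimated correlation). Of the ribosomal protein genes, 2 of 55 were lower and 53 did not pass (adjusted p = 0.000299, or adjusted p = 0.831 with an estimated correlation). *TP53* fell (21.4 ± 7.35 against 64.4 ± 6.4 CPM, adjusted p = 5.34e-06) and *CDKN1A* rose (351 ± 47 against 47.4 ± 13.7 CPM, adjusted p = 1.35e-07). The other counts did not change when adjusted over the list alone.

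Chemical conversion from the primed state was examined by comparing ccTSC with RUES2. From no count in RUES2, *SIGLEC5*, which shares sequence with *SIGLEC14*, reached 658 ± 86.6 CPM (at least 13225-fold higher) and the transcriptional cofactor gene *VGLL1* 569 ± 121 CPM (at least 11378-fold). They were followed by the steroid dehydrogenase gene *HSD3B1* (485 ± 174 CPM, at least 9922-fold) and the pregnancy glycoprotein genes *PSG4* and *PSG5*, which share sequence with each other. *GATA2* (436 ± 86.3 against 0.671 ± 0.302 CPM, adjusted p = 3.12e-14) and *GATA3* (383 ± 112 against 0.266 ± 0.108 CPM, adjusted p = 9.96e-15) rose as well. *TP63* (41.9 ± 7.13 against 0.0993 ± 0.00337 CPM, adjusted p = 6.89e-11) and *KRT7* (749 ± 164 against 11.6 ± 4.04 CPM, adjusted p = 6.11e-10) did so too. *POU5F1* fell (0.163 ± 0.164 against 1877 ± 309 CPM, adjusted p = 1.91e-13). *ZIC3*, a transcription factor gene of primed cells, went from 128 ± 26.8 CPM to no count (at least 2861-fold lower), as did *OLFM1* and *SALL1*. In all, 3541 genes were upregulated and 3308 downregulated in ccTSC compared to RUES2.

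Of the cytotrophoblast and trophoblast stem genes, 26 of 27 were higher and 1 did not pass (camera adjusted p = 8.15e-15, or adjusted p = 0.000669 with an estimated correlation). Core pluripotency genes were lower for 19 of 20 (camera adjusted p = 8.15e-15, or adjusted p = 0.00353 with an estimated correlation). Primed pluripotency genes were lower for 16 of 17 (camera adjusted p = 4.15e-10, or adjusted p = 0.000549 with an estimated correlation). In each list 1 did not pass. The de novo DNA methyltransferase gene *DNMT3B* was among the lower core genes (107 ± 29.5 against 2095 ± 891 CPM, adjusted p = 6.29e-11). Syncytiotrophoblast genes were higher for 22 of 27 and not passing for 5, or 23 higher adjusted over the list alone (camera adjusted p = 6.38e-07, or adjusted p = 0.399 with an estimated correlation). Their levels varied between libraries, with *CGB5*, of the chorionic gonadotropin cluster, at 53.7 ± 102 CPM. Extravillous genes had 13 higher, 1 lower and 8 not passing (camera adjusted p = 0.00245, or adjusted p = 0.276 with an estimated correlation). *HLA-G* was one of the 13 (90.5 ± 26.7 against 2.15 ± 0.874 CPM, adjusted p = 3.63e-09).

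In ccTSC against RUES2, the spindle checkpoint and kinetochore list had 28 of 45 lower, 0 higher and 17 not passing (camera adjusted p = 6.52e-07, or adjusted p = 0.42 with an estimated correlation). *BUB1B* (32.1 ± 7.45 against 211 ± 18.4 CPM, adjusted p = 5.62e-09) and *MAD2L1* (35.7 ± 2.43 against 197 ± 31.3 CPM, adjusted p = 4.74e-09), both in it, encode checkpoint proteins that hold anaphase until chromosomes attach. DNA replication genes had 23 of 34 lower, 1 higher and 10 not passing (adjusted p = 2.55e-06, or adjusted p = 0.42 with an estimated correlation). DNA damage checkpoint and homologous recombination genes had 22 of 47 lower, 1 higher and 24 not passing (adjusted p = 0.000484, or adjusted p = 0.42 with an estimated correlation). Cohesin genes had 6 of 17 lower, 1 higher and 10 not passing (adjusted p = 0.0458, or adjusted p = 0.53 with an estimated correlation). Ribosomal protein genes had 0 lower, 0 higher and 55 not passing, with a list median of -0.45 on the log2 scale (adjusted p = 0.0306, or adjusted p = 0.805 with an estimated correlation). *TP53* fell (22.2 ± 3.17 against 130.0 ± 24.8 CPM, adjusted p = 6.25e-09). The p53 target list, in contrast, had 17 of 33 higher, 2 lower and 14 not passing (camera adjusted p = 0.000446, or adjusted p = 0.42 with an estimated correlation). *CDKN1A* was among the higher ones (488 ± 172 against 15.8 ± 5.8 CPM, adjusted p = 1.64e-10).

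Lysosome genes were higher for 30 of 33, lower for 1 and not passing for 2 (camera adjusted p = 4.92e-10, or adjusted p = 0.238 with an estimated correlation). The cathepsin gene *CTSB* stood at 1117 ± 26.1 against 65 ± 15 CPM (log2 fold change 4.10, SE 0.28, adjusted p = 3.05e-11). Autophagy genes had 15 higher, 2 lower and 31 not passing (adjusted p = 0.00814, or adjusted p = 0.42 with an estimated correlation). Interferon response and cGAS-STING genes had 19 higher, 3 lower and 10 not passing (camera adjusted p = 0.00518, or adjusted p = 0.42 with an estimated correlation). *IFI6*, an interferon-induced gene, led them (920.3 ± 199.7 against 4.38 ± 1.97 CPM, adjusted p = 2.68e-10). The endogenous retroviral list had 7 of 8 higher and 1 not passing (adjusted p = 0.000484, or adjusted p = 0.255 with an estimated correlation). Immediate early and dissociation stress genes had 12 of 19 higher, 1 lower and 6 not passing, or 15 and 1 adjusted over the list alone (adjusted p = 0.0249, or adjusted p = 0.545 with an estimated correlation). All lists of this comparison other than these and the syncytiotrophoblast list had the same counts adjusted over the list alone.

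The other primed route was examined by comparing pdTSC with RUES2. *SIGLEC5* (599 ± 221 CPM, at least 11937-fold), *VGLL1* (549 ± 338 CPM, at least 10986-fold) and *SIGLEC6* (232 ± 25.8 CPM, at least 4689-fold) rose from no count. *GATA2* (457 ± 136 against 0.671 ± 0.302 CPM, adjusted p = 2.8e-14), *GATA3* (338 ± 105 against 0.266 ± 0.108 CPM, adjusted p = 1.24e-14) and *KRT7* (968 ± 301 against 11.6 ± 4.04 CPM, adjusted p = 3.29e-10) rose. *POU5F1* fell (0.234 ± 0.314 against 1877 ± 309 CPM, adjusted p = 2.64e-13), and *ZIC3* and the muscle actinin gene *ACTN3* were without a count in pdTSC. The imprinted gene *PEG3* had no count in RUES2 and reached 197 ± 236 CPM in pdTSC, with an SD above its mean. In all, 3462 genes were upregulated and 3107 downregulated in pdTSC compared to RUES2. Without pdTSC 1 and 3, left out after the data were seen, 6837 genes differed in place of 6569.

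Cytotrophoblast and trophoblast stem genes were higher for 25 of 27 and not passing for 2 (camera adjusted p = 4.19e-15, or adjusted p = 0.00053 with an estimated correlation). Core pluripotency genes were lower for 19 of 20 with 1 not passing (camera adjusted p = 9.81e-15, or adjusted p = 0.00369 with an estimated correlation). Primed pluripotency genes were lower for 15 of 17 with 2 not passing (camera adjusted p = 1.96e-10, or adjusted p = 0.000447 with an estimated correlation). Syncytiotrophoblast genes had 24 higher, 1 lower and 2 not passing, or 24 and 2 adjusted over the list alone (camera adjusted p = 2.12e-07, or adjusted p = 0.355 with an estimated correlation). Extravillous genes had 13 higher, 2 lower and 7 not passing (camera adjusted p = 0.0069, or adjusted p = 0.355 with an estimated correlation). Spindle checkpoint and kinetochore genes were lower for 20 of 45 and not passing for 25 (camera adjusted p = 6.95e-05, or adjusted p = 0.586 with an estimated correlation). *BUB1B* stood at 43 ± 18 against 211 ± 18.4 CPM (log2 fold change -2.29, SE 0.26, adjusted p = 6.93e-08). DNA replication genes had 17 of 34 lower, 1 higher and 16 not passing (adjusted p = 0.000255, or adjusted p = 0.586 with an estimated correlation). DNA damage genes had 14 of 47 lower, 1 higher and 32 not passing (adjusted p = 0.0111, or adjusted p = 0.586 with an estimated correlation). *TP53* fell (27 ± 9.02 against 130.0 ± 24.8 CPM, adjusted p = 3.7e-08).

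Lysosome genes were higher for 27 of 33, lower for 1 and not passing for 5 (camera adjusted p = 7.44e-09, or adjusted p = 0.256 with an estimated correlation). The p53 targets were higher for 16 of 33 with 2 lower and 15 not passing (camera adjusted p = 0.000255, or adjusted p = 0.418 with an estimated correlation). *PHLDA3*, a repressor of the AKT kinase, was one of them (179.8 ± 25.3 against 30 ± 9.01 CPM, adjusted p = 5.21e-09). Autophagy genes had 14 higher, 2 lower and 32 not passing (adjusted p = 0.0152, or adjusted p = 0.485 with an estimated correlation). Interferon response genes had 12 higher, 2 lower and 18 not passing (adjusted p = 0.0331, or adjusted p = 0.586 with an estimated correlation). The endogenous retroviral list had 7 of 8 higher and 1 not passing (adjusted p = 0.000188, or adjusted p = 0.222 with an estimated correlation). The unfolded protein and integrated stress response list had 13 of 26 higher, 2 lower and 11 not passing (adjusted p = 0.0257, or adjusted p = 0.586 with an estimated correlation). Immediate early genes had 9 of 19 higher and 10 not passing (adjusted p = 0.0441, or adjusted p = 0.586 with an estimated correlation). Without pdTSC 1 and 3 both lists had an adjusted p of 0.174. Apart from the syncytiotrophoblast list, the counts were the same adjusted over the list alone. In pdTSC 1, 6 of 18 amnion and 5 of 18 mesenchyme genes were at 5 CPM or more and at least 2-fold above the highest of the other 15 TSC libraries, and the remaining members were not. The amnion gene *GABRP* was at 147 CPM against at most 0.639 CPM and the collagen gene *COL6A3* at 819 CPM against at most 8.74 CPM.

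BAP cells were compared with RUES2 to describe the differentiation without stem cell culture. The chorionic gonadotropin genes *CGB8* and *CGB5* rose from no count, *CGB8* to 600.5 ± 474 CPM (at least 12566-fold) and *CGB5* to 497 ± 413 CPM (at least 10419-fold), and *CGA* stood at 1366 ± 1304 against 0.0321 ± 0.0556 CPM. Reads of the near-identical CGB genes could be divided among them in counting. *KRT7* (2326 ± 1373 against 11.6 ± 4.04 CPM, adjusted p = 5.31e-11) and *GATA3* (199 ± 48.9 against 0.266 ± 0.108 CPM, adjusted p = 2.8e-14) rose. *TP63*, a factor of the stem state, was at 1.1 ± 0.537 against 0.0993 ± 0.00337 CPM (log2 fold change 3.39, SE 0.68, adjusted p = 0.000165). The amnion gene *GABRP*, a GABA receptor subunit, rose (2862 ± 669.8 against 5.83 ± 2.12 CPM, adjusted p = 0.000794). *POU5F1* fell (0.18 ± 0.151 against 1877 ± 309 CPM, adjusted p = 2.29e-13), and *TDGF1*, *SOX2* and *VRTN* were without a count, *SOX2* being at least 7238-fold lower. In all, 3171 genes were upregulated and 3172 downregulated in BAP cells compared to RUES2.

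Amnion genes were higher for 14 of 18, lower for 1 and not passing for 3 (camera adjusted p = 5.23e-05, or adjusted p = 0.264 with an estimated correlation). Among them was the transcription factor gene *ISL1* (20.7 ± 1.96 against 0.247 ± 0.0783 CPM, adjusted p = 1.89e-05). Mesenchyme genes had 10 of 18 higher, 1 lower and 7 not passing (camera adjusted p = 0.00711, or adjusted p = 0.387 with an estimated correlation). The proteoglycan gene *LUM* was one of them (698 ± 245 against 0.345 ± 0.194 CPM, adjusted p = 1.2e-08). Syncytiotrophoblast genes had 23 of 27 higher and 4 not passing, or 24 higher adjusted over the list alone (camera adjusted p = 4.37e-09, or adjusted p = 0.264 with an estimated correlation). Extravillous genes had 16 of 22 higher, 1 lower and 5 not passing (camera adjusted p = 0.000234, or adjusted p = 0.173 with an estimated correlation). The matrix protease gene *MMP2* was among the higher ones (2459 ± 741 against 48.2 ± 2.47 CPM, adjusted p = 1.92e-05). Cytotrophoblast genes had 20 of 27 higher, 2 lower and 5 not passing (camera adjusted p = 4.91e-09, or adjusted p = 0.00742 with an estimated correlation). *HLA-G* did not pass (3.64 ± 1.48 against 2.15 ± 0.874 CPM, adjusted p = 0.144). All 20 core pluripotency genes were lower (camera adjusted p = 6.65e-17, or adjusted p = 0.00247 with an estimated correlation). So were 16 of 17 primed pluripotency genes with 1 not passing (camera adjusted p = 3.91e-09, or adjusted p = 0.000922 with an estimated correlation).

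In BAP cells p53 targets were higher for 20 of 33, lower for 2 and not passing for 11 (camera adjusted p = 0.00102, or adjusted p = 0.389 with an estimated correlation). *CDKN1A* was one of the 20 (485 ± 111 against 15.8 ± 5.8 CPM, adjusted p = 2.09e-10). Lysosome genes had 20 higher, 2 lower and 11 not passing (adjusted p = 2.75e-05, or adjusted p = 0.387 with an estimated correlation). Interferon response genes had 19 higher, 3 lower and 10 not passing (adjusted p = 0.000994, or adjusted p = 0.387 with an estimated correlation). Unfolded protein and integrated stress response genes had 9 higher, 4 lower and 13 not passing (adjusted p = 0.0193, or adjusted p = 0.54 with an estimated correlation). The endogenous retroviral list had 6 higher, 1 lower and 1 not passing (adjusted p = 0.004, or adjusted p = 0.339 with an estimated correlation). Spindle checkpoint and kinetochore genes had 8 of 45 lower, 1 higher and 36 not passing (adjusted p = 0.0254, or adjusted p = 0.633 with an estimated correlation). Of all 15359 genes, 3172 were lower. DNA replication genes had 10 of 34 lower, 1 higher and 23 not passing (adjusted p = 0.00863, or adjusted p = 0.622 with an estimated correlation). Ribosomal protein genes had 2 of 55 lower and 53 not passing (adjusted p = 0.0253, or adjusted p = 0.735 with an estimated correlation). Counts over the list alone differed only for the syncytiotrophoblast list.

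**Figure D3:**
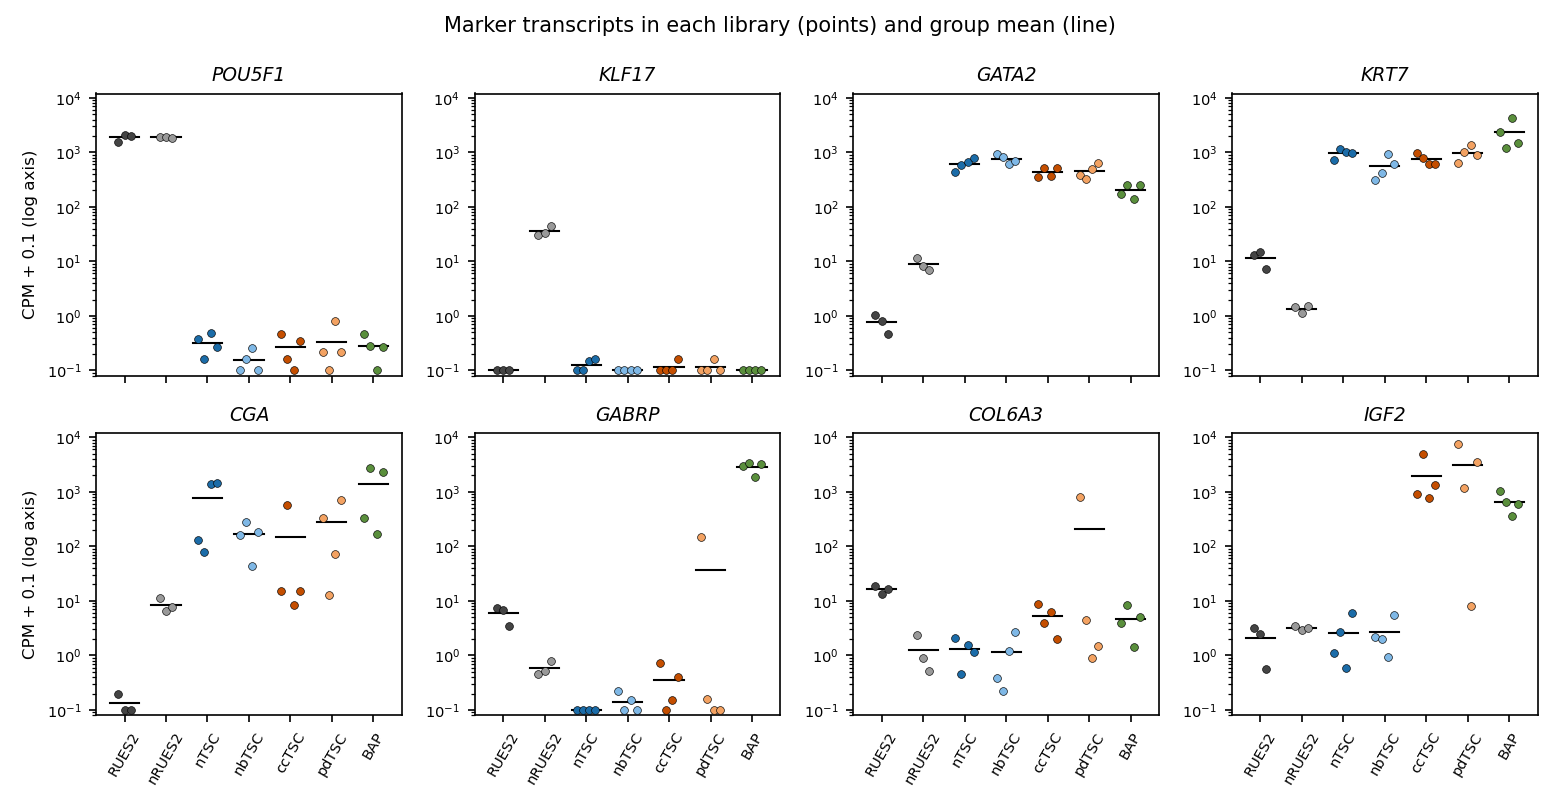
CPM + 0.1 on a log axis for 8 transcripts, 1 point per library with a line at the group mean, in the 7 groups on the horizontal axis. *POU5F1* is high in RUES2 and nRUES2 only, *KLF17* in nRUES2, *GABRP* in the 4 BAP libraries and, at 147 CPM, in 1 pdTSC library, and *COL6A3* reaches 819 CPM in the same pdTSC library.

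The parts common to both starting states were counted from comparisons that share no library. nTSC against nRUES2 and ccTSC against RUES2 had 3644 genes called in the same direction, 2078 higher and 1566 lower, where independent lists would give 806 and 642. In opposite directions were 352 against 1441. nbTSC against nRUES2 and pdTSC against RUES2 had 3626, with 2084 higher and 1542 lower against 804 and 593, and 333 opposite against 1382. In a test of the difference itself, the change differed between nTSC and ccTSC derivation for 4524 genes and between nbTSC and pdTSC derivation for 4397. This difference of changes also holds the difference between the starting states, nRUES2 and RUES2, where 5502 genes were called. The collagen gene *COL1A1* rose in nTSC (log2 fold change 3.71, SE 0.39) and fell in ccTSC (log2 fold change -1.68, SE 0.33; adjusted p of the difference = 2.08e-08). With each library of a group left out in turn, mean *COL1A1* was 4.25 to 4.90 CPM in nRUES2 and 175 to 201.5 CPM in RUES2. It was 53.5 to 65.7 CPM in nTSC and 47.8 to 65.2 CPM in ccTSC. The starting cells thus differed, while the TSC ended at similar levels. *CDX2* was low everywhere. It fell from 1.17 ± 0.472 CPM in nRUES2 to 0.0421 ± 0.0541 CPM in nTSC and 0.0853 ± 0.104 CPM in nbTSC. It rose from no count in RUES2 to 0.752 ± 1.03 CPM in ccTSC (at least 13.6-fold) and 0.774 ± 0.779 CPM in pdTSC (at least 15.2-fold). The adjusted p of the difference was 0.000866 for nTSC against ccTSC and 0.00145 for nbTSC against pdTSC, and at most 0.00315 and 0.00512 with any library of these groups left out. The levels rest on single libraries: without ccTSC 1 the ccTSC mean was 0.245 CPM (at least 4.98-fold), and without pdTSC 2 the pdTSC mean was 0.495 CPM (at least 9.91-fold). Without nTSC 4 and without nbTSC 3 the means of their groups were 0.0183 and 0.0428 CPM, and without nRUES2 3 the fall in nbTSC had an adjusted p of 0.0571.

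Naive-derived TSC (nTSC and nbTSC, n = 8) were compared with primed-derived TSC (ccTSC and pdTSC, n = 8) to ask what the starting state leaves different. The growth factor gene *IGF2*, which is imprinted, was low in naive-derived TSC and high in primed-derived TSC (2.51 ± 2.04 against 2531 ± 2619.7 CPM, adjusted p = 2.4e-06), except in pdTSC 3 at 8.07 CPM. The pregnancy glycoprotein genes *PSG1* (3.1 ± 2.64 against 232 ± 196 CPM, adjusted p = 6.13e-06) and *PSG11* were lower in naive-derived TSC. The glucuronosyltransferase gene *UGT1A6* (0.209 ± 0.191 against 62.9 ± 60.2 CPM, adjusted p = 5.55e-06), the oxytocin receptor gene *OXTR* and *OCIAD2* (1.58 ± 1.11 against 54.6 ± 33.1 CPM, adjusted p = 3.88e-07) were lower as well. Both the PSG and the UGT1A genes share sequence with their neighbours, so reads could be divided among them in counting. Higher in naive-derived TSC were the zinc finger genes *ZNF208* (29.8 ± 11.8 against 2.53 ± 4.0 CPM, adjusted p = 0.000157) and *ZNF558* (23.7 ± 4.21 against 3.4 ± 6.26 CPM, adjusted p = 0.000162). *CCDC144A*, *JSRP1*, *JADE2* and *NKD2*, a Wnt pathway antagonist (23.9 ± 8.62 against 5.71 ± 2.74 CPM, adjusted p = 4.79e-06), were higher too. In all, 435 genes were upregulated and 1677 downregulated in naive-derived TSC compared to primed-derived TSC. The number was 2358 without pdTSC 1 and 3 in place of 2112.

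Interferon response and cGAS-STING genes were lower in naive-derived TSC for 20 of 32 and not passing for 12 (camera adjusted p = 3.02e-08, or adjusted p = 0.473 with an estimated correlation). Among them were *IFIT1* (1.87 ± 1.19 against 24.6 ± 16.5 CPM, adjusted p = 2.39e-05) and *IFIT3* (0.405 ± 0.307 against 7.67 ± 5.77 CPM, adjusted p = 7.01e-06), which encode antiviral proteins. Spindle checkpoint and kinetochore genes lay higher by camera although 1 of 45 was called and 44 did not pass (camera adjusted p = 2.13e-09, or adjusted p = 0.5 with an estimated correlation). The called member was *KNL1*, a kinetochore scaffold gene (71.8 ± 16.1 against 34.9 ± 16.9 CPM, adjusted p = 0.000336), and *BUB1B* stayed under 2-fold (71.5 ± 15.2 against 37.6 ± 14 CPM, adjusted p = 0.000217). DNA damage genes lay higher as well, with 1 of 47 called and 46 not passing (adjusted p = 6.76e-06, or adjusted p = 0.5 with an estimated correlation). So did DNA replication genes, with 2 of 34 called and 32 not passing (adjusted p = 1.15e-05, or adjusted p = 0.584 with an estimated correlation), and hypoxia and glycolysis genes, with 2 of 26 called and 24 not passing (adjusted p = 0.00104, or adjusted p = 0.584 with an estimated correlation). Lysosome genes lay lower with 4 of 33 called and 29 not passing (adjusted p = 0.000782, or adjusted p = 0.584 with an estimated correlation). The 4 include the cathepsin gene *CTSD* (292 ± 47.8 against 672 ± 248 CPM, adjusted p = 5.69e-05). The DNA methylation list had 1 of 14 higher and 13 not passing (adjusted p = 0.00633, or adjusted p = 0.5 with an estimated correlation). The higher one was *DNMT3L*, at a low level in both (9.5 ± 7.05 against 0.42 ± 0.681 CPM, adjusted p = 3.03e-06). Ribosomal protein genes had 0 called of 55 (adjusted p = 0.028, or adjusted p = 0.702 with an estimated correlation), and their adjusted p was 0.193 without pdTSC 1 and 3. Every list of this comparison gave the same counts adjusted over the list alone.

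The trophoblast lists had called members in both directions and did not pass camera. Cytotrophoblast and trophoblast stem genes had 1 higher, 4 lower and 22 not passing (adjusted p = 0.926, or adjusted p = 0.953 with an estimated correlation). Syncytiotrophoblast genes had 1 higher, 9 lower and 17 not passing (adjusted p = 0.217, or adjusted p = 0.702 with an estimated correlation). Extravillous genes had 2 higher, 9 lower and 11 not passing (adjusted p = 0.0602, or adjusted p = 0.584 with an estimated correlation). Of the single genes, *GATA3* (292 ± 67 against 361 ± 103 CPM, adjusted p = 0.162), *TP63* (36.6 ± 13.2 against 48.4 ± 20.4 CPM, adjusted p = 0.198) and *KRT7* (771 ± 306 against 858 ± 253 CPM, adjusted p = 0.57) did not pass. The germline gene *SYCP3* (37.4 ± 23.7 against 0.679 ± 1.26 CPM, adjusted p = 4.49e-05) and *DPPA3*, a gene of naive cells and germ cells (43.8 ± 19.7 against 5.97 ± 7.84 CPM, adjusted p = 0.000196), were higher in naive-derived TSC. The naive pluripotency list had 7 of 24 higher, 2 lower and 15 not passing (camera adjusted p = 0.0544, or adjusted p = 0.5 with an estimated correlation). The amnion gene *GABRP* was called lower (0.0212 ± 0.0427 against 18.5 ± 52 CPM, adjusted p = 0.045), which rests on pdTSC 1 at 147 CPM.

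Within the naive origin, nbTSC were compared with nTSC to ask what the blastoid step changes. Of the called genes, 3 passed the rule for naming, and all 3 were lower in nbTSC. They were *DENR*, a translation reinitiation factor gene (77.1 ± 10.3 against 170 ± 30.9 CPM, adjusted p = 0.00925), and *ALG8*, a gene of protein glycosylation (27 ± 3.34 against 55.7 ± 3.47 CPM, adjusted p = 0.00925). *DCAF4L2* was the other (0.232 ± 0.359 against 23.4 ± 23.7 CPM, adjusted p = 0.0293). In all, 2 genes were upregulated and 6 downregulated in nbTSC compared to nTSC by edgeR, with 1101 at an unadjusted p below 0.05. DESeq2 called 37, 16 higher and 21 lower. The balance of directions was unstable, with 6 higher and 3 lower without nbTSC 4 and 0 higher and 8 lower without nTSC 2. The count was 0 when edgeR was fitted to these 8 libraries alone, 2 without nbTSC 2, 4 without nTSC 3, nTSC 4 or nbTSC 1, 13 without nTSC 1 and 23 without nbTSC 3. Syncytiotrophoblast genes lay lower in nbTSC with none of 27 called (camera adjusted p = 5.02e-05, or adjusted p = 0.987 with an estimated correlation). *CGA* stood at 168 ± 97.9 against 772 ± 773 CPM (log2 fold change -2.20, SE 1.28, adjusted p = 0.77). Hypoxia and glycolysis genes lay higher with none of 26 called (camera adjusted p = 0.0213, or adjusted p = 0.987 with an estimated correlation). *KRT7* did not pass (573 ± 277 against 970.0 ± 191 CPM, adjusted p = 0.665). Adjusted over the list alone, these 2 lists again had no called member.

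Within the primed origin, pdTSC were compared with ccTSC, and no gene passed. edgeR called 0 genes, with 1457 at an unadjusted p below 0.05 and a smallest adjusted p of 0.132, and DESeq2 called 26. *LIN28A*, an RNA-binding protein gene of early embryonic cells, stood at 193 ± 81.2 against 86.6 ± 32.7 CPM (log2 fold change 1.16, SE 0.27, adjusted p = 0.257). *HSD3B1* stood at 215 ± 61.5 against 485 ± 174 CPM (log2 fold change -1.18, SE 0.35, adjusted p = 0.364). The spread was wide in pdTSC for some genes, and *COL3A1* was 196 ± 380.3 against 6.05 ± 1.04 CPM, with pdTSC 1 at 766 CPM. Leaving out pdTSC 2 gave 270 genes, leaving out ccTSC 2 gave 20 and leaving out ccTSC 1 gave 4.

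Without a called member, 10 lists still passed camera between pdTSC and ccTSC, each with adjusted p = 0.593 with an estimated correlation. Higher in pdTSC were ribosomal protein (adjusted p = 5.73e-12), DNA replication (8.15e-08), spindle checkpoint and kinetochore (2.98e-07), hypoxia and glycolysis (8.32e-07), DNA damage (1.09e-05), unfolded protein and integrated stress response (0.0037), cohesin (0.0194) and DNA methylation genes (0.0364). Lower were lysosome (0.000202) and interferon response genes (0.00275). Among their members, the glycolysis gene *GAPDH* stood at 4610.5 ± 1683 against 2861 ± 374 CPM (log2 fold change 0.69, SE 0.22, adjusted p = 0.375) and *MAD2L1* at 54.2 ± 21.1 against 35.7 ± 2.43 CPM (log2 fold change 0.60, SE 0.21, adjusted p = 0.397). Without pdTSC 1 and 3 only the ribosomal protein list was kept, and the lysosome, spindle, hypoxia and unfolded protein lists turned direction. Adjusted over the list alone, the lists of this comparison also had 0 called members.

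BAP cells were compared with primed-derived TSC (n = 8) to set the differentiation beside the stem cell routes from the same primed cells. *IGFBP5*, an insulin-like growth factor binding protein gene (4013 ± 1874 against 0.797 ± 1.27 CPM, adjusted p = 9.6e-11), and *GABRP* (2862 ± 669.8 against 18.5 ± 52 CPM, adjusted p = 7.87e-06), both of the amnion list, were higher in BAP cells. So were the mesenchyme genes *LUM* (698 ± 245 against 8.33 ± 5.67 CPM, adjusted p = 1.92e-09) and *COL1A1* (553 ± 198 against 79 ± 37.7 CPM, adjusted p = 3.08e-09). The chemokine gene *CXCL12* had no count in the 8 TSC libraries and 59.5 ± 27.9 CPM in BAP cells (at least 2658-fold), and *OSR1*, *NDNF*, *NTRK2* and *GYPC* followed. *TP63* (1.1 ± 0.537 against 48.4 ± 20.4 CPM, adjusted p = 2.49e-10) and *SIGLEC6* (0.767 ± 0.247 against 209 ± 72.3 CPM, adjusted p = 1.06e-12) were lower in BAP cells. The endocytic receptor gene *LRP2* (15.5 ± 9.94 against 1230.1 ± 361 CPM, adjusted p = 9.05e-11) and *HLA-G* (3.64 ± 1.48 against 70.7 ± 29.5 CPM, adjusted p = 9.07e-09) were lower too. *PEG3* had no count in BAP cells against 113 ± 182 CPM (at least 2488-fold lower), and *PSG1*, *SIGLEC14*, *TMEM45B*, *MAGEA8* and *ABHD12B* were the next lowest. In all, 1984 genes were upregulated and 2440 downregulated in BAP cells compared to primed-derived TSC.

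Amnion genes had 13 of 18 higher, 1 lower and 4 not passing (camera adjusted p = 0.000257, or adjusted p = 0.458 with an estimated correlation). Mesenchyme genes had 12 higher, 2 lower and 4 not passing, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.000651, or adjusted p = 0.458 with an estimated correlation). Both lists also held genes that were high in pdTSC 1 among the TSC. Cytotrophoblast and trophoblast stem genes were lower for 15 of 27, higher for 2 and not passing for 10 (camera adjusted p = 1.45e-05, or adjusted p = 0.12 with an estimated correlation). *KRT7* was higher (2326 ± 1373 against 858 ± 253 CPM, adjusted p = 0.000224). Lysosome genes were lower for 15 of 33 with 18 not passing (camera adjusted p = 0.000184, or adjusted p = 0.612 with an estimated correlation). *CTSH* was among them (20.4 ± 11.4 against 441 ± 133 CPM, adjusted p = 2.45e-09). Germline genes were lower for 13 of 21, higher for 2 and not passing for 6 (adjusted p = 0.0277, or adjusted p = 0.612 with an estimated correlation). Naive pluripotency genes were lower for 13 of 24, higher for 1 and not passing for 10 (adjusted p = 0.0121, or adjusted p = 0.458 with an estimated correlation). Spindle checkpoint and kinetochore genes were higher for 7 of 45 with 38 not passing (adjusted p = 0.000184, or adjusted p = 0.836 with an estimated correlation). DNA replication genes were higher for 6 of 34 with 1 lower and 27 not passing (adjusted p = 0.0102, or adjusted p = 0.977 with an estimated correlation). The 6 include *RRM2*, a ribonucleotide reductase subunit gene (193 ± 36.9 against 43.9 ± 27.6 CPM, adjusted p = 6.34e-06). *TP53* was higher (73.3 ± 10.2 against 24.6 ± 6.76 CPM, adjusted p = 2.57e-07). The remaining lists had equal counts adjusted over the list alone.

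Because the series asks about chromosomal instability, expression was also summarised by chromosome, which is an indirect measure; karyotypes were not analysed here. Between groups, 2 chromosomes shifted. Genes of chromosome 19 lay higher in nRUES2 than in RUES2, by a median of 0.33 on the log2 scale relative to all autosomal genes, with 268 of 1164 genes higher and 125 lower (camera adjusted p = 0.0093, and adjusted p = 0.648 with an estimated correlation). The 254 zinc finger genes of chromosome 19 had a median of 0.70 with 92 higher and 4 lower, its other 910 genes a median of 0.22, and the 272 zinc finger genes elsewhere a median of 0.07. Its members of smallest p were *ZNF600* (chromosome 19, 52764164 to 52833645 of the GRCh38.p14 annotation; log2 fold change 5.18, SE 0.33, adjusted p = 1.35e-11), *NLRP2* (54965284 to 55001138; 3.65, SE 0.23) and *ABHD8* (17292131 to 17303425; -4.54, SE 0.31). Chromosome 19 was no longer called without genes whose symbol starts with ZNF or ZFP, a choice made after the data were seen. Nor was it over genes with a mean of at least 10 CPM, or without genes called at 4-fold or more.

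Genes of chromosome X lay lower in naive-derived than in primed-derived TSC, by a median of -0.41, with 15 of 605 genes higher and 145 lower (camera adjusted p = 3.9e-05, and adjusted p = 0.508 with an estimated correlation). The deubiquitinase gene *USP11* (X, 47233009 to 47248328; log2 fold change -1.94, SE 0.18, adjusted p = 5.37e-07), the potassium channel subunit gene *KCNE5* (109623700 to 109625172; -4.08, SE 0.44) and *GPR143* (9725346 to 9778602; -1.84, SE 0.21) had the smallest p. Chromosome X stayed shifted in the 3 settings in which chromosome 19 was lost, with medians of -0.41, -0.38 and -0.36. With the estimated correlation neither chromosome stayed shifted, and without nbTSC 3 or without nbTSC 4 the number over all comparisons was 5.

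Single TSC libraries differed by chromosome within their groups. Genes of chromosome 7 lay higher by a median of 0.53 in ccTSC 1 and 0.49 in pdTSC 2, with 83.1% and 81.5% of 720 genes above the median of the other TSC libraries. The other 14 libraries lay between -0.08 and 0.00. The shifts passed camera (adjusted p of 8.28e-17 and 4.86e-18, or adjusted p = 0.336 for both with an estimated correlation). Each of these tests sets 1 library against the other 15, which alone supply the spread, so that its p reflects the genes within 1 library and not replication. Chromosome 20 lay higher in nTSC 3 (0.34, adjusted p = 4.86e-18, and adjusted p = 0.0453 with an estimated correlation). In nbTSC 1 and nbTSC 2, chromosome 4 (-0.32 and -0.37), chromosome 13 (-0.24 and -0.26) and chromosome 15 (-0.27 and -0.25) lay lower, and chromosome 13 lay higher in nTSC 1 (0.23). Chromosome X lay higher in ccTSC 1 (0.37), ccTSC 3 (0.27), ccTSC 4 (0.35) and pdTSC 2 (0.34). With an estimated correlation, chromosome 20 in nTSC 3 alone stayed below 0.05. This correlation is taken from the other 15 libraries. For chromosomes 4, 7, 13, 15 and X these include a library with a shift of the same chromosome, which can raise it. The values therefore cannot rank chromosome 7 below chromosome 20.

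**Figure D4:**
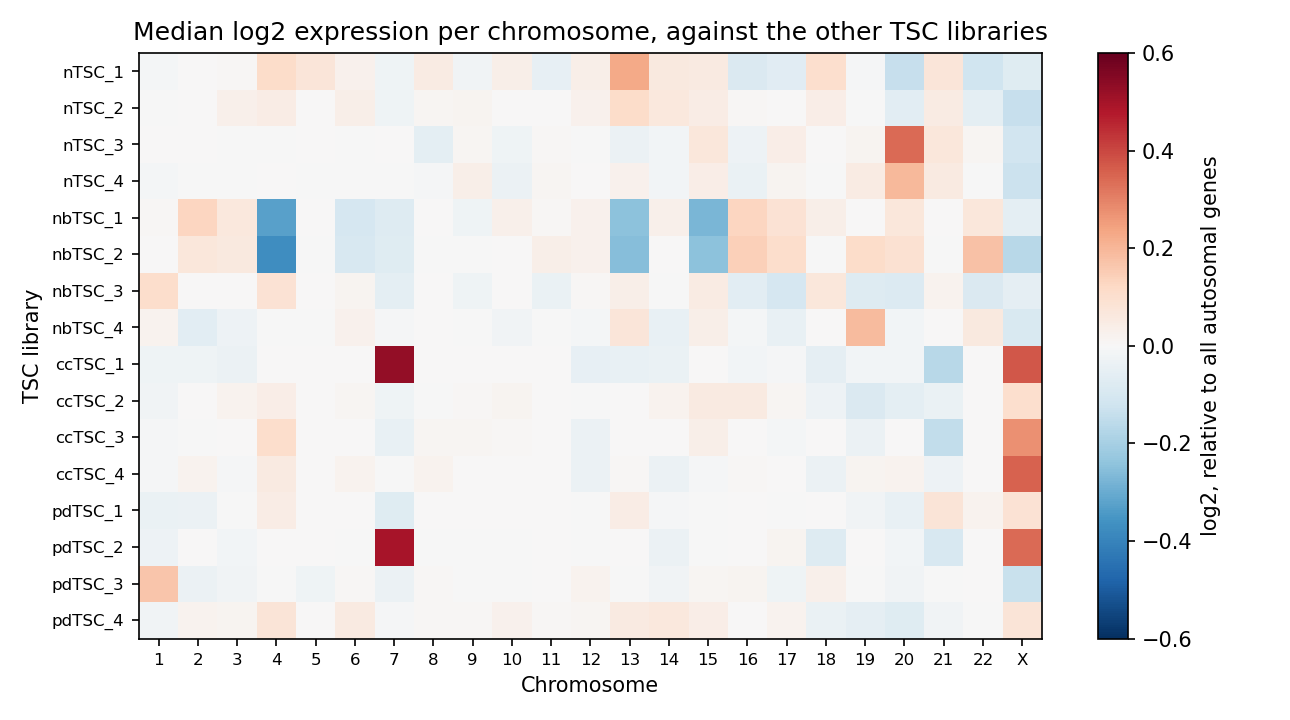
Median log2 expression of the genes of each chromosome (horizontal axis) in each of the 16 TSC libraries (vertical axis), relative to the other TSC libraries and to all autosomal genes, with red above 0 and blue below. Chromosome 7 reaches 0.53 in ccTSC 1 and 0.49 in pdTSC 2, and chromosome 4 falls to -0.32 and -0.37 in nbTSC 1 and nbTSC 2.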

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

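The tests of chromosome 7 by expression level and by chromosome side, both tests of pdTSC 1 and the test of a swap of pdTSC 3 were chosen after the results were seen; the others were chosen before. In 19 of 167 overlapping groups of 4 or 8 libraries, 1 library stood apart by Dixon's gap test, whose chance rate is unknown here.

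Chromosome 7 genes lay higher in ccTSC 1 (median log2 0.5282; next library -0.00) and in pdTSC 2 (0.4939; next library -0.01) than in the rest of their groups. Low depth was argued against, since with all TSC libraries thinned to the smallest total the lower of the medians was 0.4954, and so was an effect of a few genes or of low counts, since over genes with a mean of at least 10 CPM it was 0.4364. A gain of the whole chromosome in both libraries may be a candidate explanation, as the lowest median on either side of the widest gap was 0.4448. This is below the 0.585 of a copy gained in every cell and 0.549 of a simulated gain. In ccTSC 1 and pdTSC 2, medians were 0.430 and 0.431 over more expressed genes but 0.680 and 0.628 over the rest. With an estimated correlation the adjusted p was 0.336 for both, and the other 42 autosome values of these libraries lay between -0.17 and 0.02. Copy number was not measured, this hypothesis was found and tested on the same data, and why both libraries share it was not tested.

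In pdTSC 3, *IGF2* stood at 8.07 CPM, *DNMT3L* at 2.09 CPM (next primed-derived library 0.32), *KNL1* at 73.03 CPM (next 41.11) and *ZNF558* at 17.82 CPM (next 6.82), nearer to naive-derived TSC. Over 24 genes on in ccTSC and off in naive-derived TSC its median share of the ccTSC level was 1.152%, where ccTSC lay between 17.4% and 168% and naive-derived libraries, each over 21 to 28 genes chosen without it, between -1.77% and 0.9993% (SD 0.923). A swap with a naive-derived library is argued against, because none of the 8 lay above 0.9993% where the lowest other pdTSC library lay at 13.7% over genes chosen in that way. A naive-derived library under a pdTSC label and a mixture of cells cannot be told apart by these genes, as its share over 5 naive genes was 29.6% against 40.6% to 173% in naive-derived libraries. A difference in culture or in the path of derivation stays open and was not tested.

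In pdTSC 1, *GABRP* stood at 147.3 CPM (next primed-derived library 0.64), *COL3A1* at 766.4 CPM (next pdTSC 6.24), *TP53* at 39.92 CPM (next 26.38) and *TP63* at 95.07 CPM (next 52.69). Of the 5 transcripts abundant in BAP cells and low in the other TSC libraries, *GABRP* (5.15% of the BAP level), *ADAMTS9* (4.14%) and *PAPPA2* (3.51%) go with a share of BAP cells, but *SLIT3* (0.255%) and *IGFBP5* (0.08784%) lie far below it, which argues against BAP cells of the measured mean composition and not against a part of them. Cells of a type outside the series could not be excluded: 5 of the 18 members of the mesenchyme list were at least 2-fold above the other 15 TSC libraries, which express 10 of the 18 at 10 CPM or more, and another list holds 1. Of its abundant genes, *COL6A3* stood at 819 CPM (4.61 CPM in BAP cells) and *VIM* at 306 CPM, while *COL1A2* stood at 2906 CPM below the highest other TSC library (4575 CPM). A change of state in part of the culture stays open and was not tested.

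Single libraries stood apart for other genes, given here as values. In ccTSC 1, *CDX2* was at 2.27 CPM (next 0.38) and *IFIT3* at 20.74 CPM (next primed-derived library 9.01), and chromosome 13 had a median of -0.04376 (next 0.00). In ccTSC 2, *CGB5* was at 206.8 CPM (next 3.19), and in ccTSC 4, *GAPDH* was at 3416 CPM (next 2724). In nbTSC 4, *GATA3* was at 434.5 CPM (next 285) and *XAGE3* at 246.7 CPM (next 106.6), and in nbTSC 2, *SIGLEC6* was at 238.3 CPM (next 170.3). In nbTSC 1, *GABRP* was at 0.12 CPM (next naive-derived library 0.05), and in pdTSC 4, *SYCP3* was at 3.62 CPM (next primed-derived library 1.26).

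Derivation from naive and from primed cells differed by a test of the difference for 4524 genes (nTSC against ccTSC) and 4397 genes (nbTSC against pdTSC). The difference between the starting states enters these counts as well. *COL1A1* moved in opposite directions, with a difference of log2 fold changes of 5.389 for nTSC against ccTSC. It did so from unlike levels in the starting cells to similar levels in the TSC. *CDX2* also moved in opposite directions, with fitted differences of -11.218 for nTSC against ccTSC and -10.372 for nbTSC against pdTSC. These depend on the default prior count of the edgeR fit, because RUES2 had no count.

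Other splits of the same libraries were fitted as a comparison with groups of the same sizes. For nRUES2 against RUES2 the 10 splits are too few for a share under 0.05; the real split gave 5635 genes, 8 lists and 1 chromosome, and the highest of the others 0, 11 and 0, with 1, 2 and 1 splits as large. Of the splits that part all 3 numbered pairs, as the real one does, the highest other gave 0 genes and 7 lists, and those that part 1 pair gave at most 0 genes and 11 lists. For genes, the real split alone reached its count (1 of 35) in nTSC (6211, highest other 0) and nbTSC (5947, 0) against nRUES2. So it did in ccTSC (6624, 1), pdTSC (5829, 9) and BAP (6212, 0) against RUES2. Of 100 drawn splits, it alone did so in naive-derived (1334, 480) and BAP (3739, 180) against primed-derived TSC. Every other split mixes the groups, which lowers its count, so these shares do not exclude chance. For nbTSC against nTSC (highest other 7) and pdTSC against ccTSC (highest other 537) the real split gave 0 genes, so 35 of 35 splits are as large by definition and the count does not bear on chance. The 537 genes came from ccTSC 1, 3 and 4 with pdTSC 2 against the rest, which points to a structure of the samples other than the route.

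For the number of gene lists called with the preset correlation, chance cannot be excluded in any of these comparisons. Splits as large were 12 of 35 in nTSC against nRUES2 (real 12, highest other 17), 17 of 35 in nbTSC against nRUES2 (11, 15), 5 of 35 in ccTSC against RUES2 (17, 18), 4 of 35 in pdTSC against RUES2 (17, 20) and 7 of 35 in BAP against RUES2 (19, 21). They were 52 of 100 in naive-derived against primed-derived TSC (8, 17), 34 of 35 in nbTSC against nTSC (2, 18), 17 of 35 in pdTSC against ccTSC (10, 16) and 54 of 100 in BAP against primed-derived TSC (8, 16). For chromosomes in naive-derived against primed-derived TSC, 10 of 100 splits gave as many as the real 1 (highest other 1), so chance cannot be excluded.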

How the results depend on the processing

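The counts without pdTSC 1 and 3 and the chromosome test without zinc finger genes were chosen after the results were seen. With the estimated correlation, 17 of 102 list calls and 0 of 2 shifted chromosomes remained; the number of shifted chromosomes was 1 over genes with a mean of at least 10 CPM, 1 without genes called at 4-fold or more and 1 without genes whose symbol starts with ZNF or ZFP, each time chromosome X and no longer chromosome 19. For nbTSC against nTSC the count of genes was 0 with only these groups and 37 by DESeq2, and for pdTSC against ccTSC it was 26 by DESeq2; the cause was not tested. Without pdTSC 1 and 3, for a cause that was not tested, 4 lists of pdTSC against ccTSC turned direction: lysosome (adjusted p = 0.788), spindle checkpoint and kinetochore (0.329), unfolded protein and integrated stress response (0.326) and hypoxia and glycolysis (0.576). A further 8 lists fell short of the threshold and 29 stayed past it in the same direction.

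Leaving out 1 library at a time gave 5167 to 5515 genes for nRUES2 against RUES2, 6213 to 6435 for nTSC and 6201 to 6486 for nbTSC against nRUES2, 6616 to 6926 for ccTSC, 6333 to 6767 for pdTSC and 6076 to 6242 for BAP cells against RUES2, 1804 to 2376 for naive-derived against primed-derived TSC and 4059 to 4567 for BAP cells against primed-derived TSC. The range was 2 to 23 for nbTSC against nTSC (23 without nbTSC 3, 13 without nTSC 1, 2 without nbTSC 2, 4 without nTSC 3, nTSC 4 or nbTSC 1) and 0 to 270 for pdTSC against ccTSC (270 without pdTSC 2, 20 without ccTSC 2, 4 without ccTSC 1). Shared genes ranged from 3506 to 3705 (nTSC and ccTSC) and from 3469 to 3724 (nbTSC and pdTSC), and shifted chromosomes from 2 to 5 (5 without nbTSC 3 or 4).

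Of the values of named genes, 943 kept their direction and side of the threshold by DESeq2 and 2 fell short, 916 and 13 with only the groups of the comparison, 938 and 7 with the replicate number as a block, and 944 and 1 with RLE scaling. With that block, 101 list calls held and 1 fell short. Gene counts in the order of the report were 5461, 6396, 6385, 6715, 6423, 6224, 2022, 6, 0 and 4375. The first, 5502 without the block, alone has numbers that may pair the libraries. The median log2 fold change of all genes in nTSC and nbTSC against nRUES2 was -0.12 and -0.11 by DESeq2, which changes the model as well as the scaling, and -0.06 and -0.05 with RLE scaling alone. Alternatives for pseudocounts and low-value filters of TPM were not run, because counts were deposited. At these depths, genes below the expression filter could not be tested.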

Other observations

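The test of genes shared between the pluripotent states and the TSC was chosen before its result was seen. By edgeR, imprinted genes went both ways in each of the 8 comparisons with called members, while DESeq2 called 1, higher, in nbTSC against nTSC, and the list passed camera in none. Between naive-derived and primed-derived TSC, 3 of 33 imprinted genes were higher, 8 lower and 22 did not pass (adjusted p = 0.512), and between nRUES2 and RUES2 6 were higher, 5 lower and 22 did not pass (adjusted p = 0.996). Hypoblast and endoderm genes had 3 higher, 6 lower and 2 not passing of 11 in nRUES2 against RUES2 (adjusted p = 0.236). Neuroectoderm genes, of the early neural fate, had 0 higher, 3 lower and 6 not passing of 9 in BAP cells against RUES2 (adjusted p = 0.106). Apoptosis genes of the *BCL2* family had 7 higher, 6 lower and 11 not passing of 24 in nRUES2 against RUES2 (adjusted p = 0.819). These 4 lists passed camera in none of the 10 comparisons. Adjusted over the list alone, the counts given were the same.

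Genes that differed between the pluripotent states were compared with genes that differed between the TSC derived from them. In the same direction were 865 genes, 174 higher and 691 lower on the naive side, where independent lists would give 420, and 245 were in opposite directions against 337. Of the 174, 39 were zinc finger genes, which make up 526 of the 15359 tested genes. As a hypothesis, part of the difference between the pluripotent states may persist in the TSC, and the 865 genes are what this predicts in a test that could have come out the other way. The correlation of the fold changes across genes was 0.27, and genes are not independent replicates. Because the states and the TSC routes differ in culture as well, a shared effect of medium stays open and was not tested.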
